A study of Mus musculus and Mus spretus with 72 samples.

How the data were processed

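Gene expression was measured on 72 arrays with 2 channels, each setting RNA of 1 male mouse against a pool of 9 C57BL6 laboratory mice of the same tissue. The labels give 5 groups in brain, in liver/kidney and in testis: dom (Mus musculus domesticus), mus (M. m. musculus), cas (M. m. castaneus), ssp (M. musculus of a sub-species the labels do not name) and spretus (M. spretus). The first 4 are called the 4 musculus groups. Mice were about 12 weeks old. In each tissue dom, mus and ssp had 6 arrays each, cas and spretus 3 each. Groups and animal numbers came from the array titles. Array 08 of mus in brain has a title that says mus and a channel label that says domesticus, so it stayed in mus and was left out as an alternative.

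The deposited values are log ratios processed by the authors, and log2 is taken here as their scale, which the sources used here do not state. Values ran from -5.714 to 5.772, a range that rules out log10 but not the natural log, under which each log2 value would be larger by a constant factor and each test the same. Scanner, background correction and normalisation are not given in the sources used here. The deposited array medians lay between -0.04 and 0.06, so the arrays had been centred near 0. The direction of the ratio is not stated either. It is taken as sample over pool, which is likely because channel 2 holds the sample and channel 1 the pool on every array, and because the pair of arrays whose labels name dyes gives the same arrangement. Were it inverted, all signs would turn together. Correlations between arrays of a tissue, over all probes, reached down to -0.179 in brain, -0.0769 in liver/kidney and -0.293 in testis, around medians of 0.0951, 0.330 and 0.165.

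Each array had 46128 spots, of which 42825 to 44832 carried a value. Neighbouring spots held the same probe in 22320 pairs, and all 16326 pairs listed in the probe table had equal identifiers. Duplicate spots correlated with a median r of 0.565 within an array (0.261 to 0.791), against 0.0706 for neighbours that were not duplicates. Pairs were averaged, 1488 single spots at row ends were dropped, and the Gapdh probe repeated over 232 pairs was averaged into 1 probe. Of the 22089 probes, 15801 had 1 gene symbol, 294 had several and 5994 were not listed and are unnamed here. The probe table holds 14386 symbols. The Entrez identifiers of 15601 probes were found in a RefSeq gene table (GRCm38.p6), and 0 symbols needed an update. Coordinates are not given, because the array's genome build is not stated. No probe sequences were used.

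Each array was centred on its median over probes. A probe was tested in a tissue where every group had at least 2 values. Linear models with 1 coefficient per group were fitted with limma 3.58.1 (lmFit, eBayes) in R 4.3.3, with tables handled by data.table (version 1.17.8). All 5 groups of a tissue shared the estimate of the spread, and animal numbers were not used as a block. The 4 contrasts per tissue were mus minus dom, cas minus the mean of dom and mus, ssp minus the mean of dom, mus and cas, and spretus minus the mean of the 4 musculus groups. A probe counted as changed at a two-sided Benjamini-Hochberg adjusted p under 0.05. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

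Expression divergence between 2 groups was the mean over probes of the squared difference of group means, minus the part that the spread between animals adds, with a jackknife standard error from leaving out each animal. Gene lists for cell types, pathways and complexes, with at least 4 measured members, were tested with limma's camera (correlation preset at 0.01) on 1 mean value per symbol, adjusted over all lists and contrasts of a tissue. The same test was repeated with the correlation estimated. Members were counted after adjustment over all genes and adjusted over the list alone. Counts of list members use the mean over a gene's probes, while a named gene is given by 1 probe, so a named member is not always among its list's changed genes. Differences between tissues were tested in 1 limma model of all arrays with the animal as a random block. Overlaps between tissues were set against the number that independent lists would share. X-linked shares were compared by Fisher's exact test.

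The genes named in the text follow a rule. For mus minus dom and for spretus, they are the 4 largest log2 changes in each direction among changed probes of a tissue, and for cas and ssp the 2 largest. A gene is represented by its probe with the smallest p. Probes with several symbols or none, RIKEN clones, Gm models, expressed sequences and LOC names were passed over. Up to 3 changed members of each list with the smallest p were added per contrast and tissue. All other genes named were chosen after their values were seen, such as list members beyond these 3 or members that passed only adjusted over the list alone (Zfy1, Usp26, Rpl38, Rps25, Spag11a, Defb2, Fgg, Ahsg and Hpx among them). The contrasts, tests, lists, naming rule and most alternatives were fixed before the data were examined. The print batches and all their alternatives, and the restriction of the tissue model to probes with a value on all arrays, were chosen after seeing the data.

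Arrays fell into batches by which spots lack a value. The labels name no batch. They are called print batches here from the shared missing spots alone, and what made arrays share them was not tested. Within a batch, 2 arrays shared a median of 45.4% of their missing spots, between batches 3.47% (average linkage clustering at height 0.8). Batch 1 held 46 arrays, batch 2 held 23, batch 3 held 2 (cas 03 in brain, spretus 02 in liver/kidney) and batch 4 held 1 (dom 01 in testis). The batches partly follow the groups. Batch 2 held the cas and spretus arrays other than those in batch 3, mus 05 and 07 and ssp 04, 05 and 06 in brain, and mus 07 and 08 in testis, and in liver/kidney cas and spretus share no batch with dom, mus or ssp. Counts within a batch are therefore given beside pooled ones where a batch holds at least 2 arrays of both groups. They use part of the same arrays, so agreement in sign with the pooled values is no second test.

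The equal animal numbers of different groups did not pair the arrays. Of 27 same-numbered pairs per tissue, correlations of deviations from the group means passed 0.1 in 1, 2 and 8 pairs in brain, liver/kidney and testis. Of 198 pairs with different numbers and groups, 9, 31 and 52 passed it. Arrays of the same animal in 2 tissues correlated with medians of 0.0234, 0.0161 and 0.0574 over the 3 pairs of tissues, 24 animals each. Alternatives were no centring, quantile normalisation, complete probes only, a robust prior, array weights, the groups of a contrast alone, 1 value per symbol, the replicate block, leaving out each array, 3 animals per group, print batch as a term or random block, and leaving out the arrays outside batches 1 and 2. The procedures were tested on simulated data in which 200 probes were changed. For mus minus dom, 72.5%, 72.5% and 76% of changes of 0.5 log2 were recovered in brain, liver/kidney and testis, and 96.5%, 98% and 98% of changes of 1. For spretus, 57%, 66% and 72.5% of changes of 0.5 were recovered. Among the probes called in these simulations, the false share ran from 2.7% (brain, mus minus dom) to 9.1% (brain, cas). With no change simulated, 0 probes were called. The simulated noise was normal and independent between probes and arrays, without batches, so it does not give the rate of false calls on the real arrays. The number of arrays limits the precision, and p-values reflect the spread between these animals, pooled over the 5 groups of a tissue. That spread was unequal between groups. In liver/kidney the mean variance was 0.0935 in spretus, 0.0607 in cas, 0.0333 in dom, 0.0307 in mus and 0.0409 in ssp. In brain it was 0.031 in spretus and 0.0852 in cas, and in testis 0.0543 in spretus and 0.0283 in cas. Pooled standard errors do not show these differences. With array weights the order of the spretus counts in brain and liver/kidney turned.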

Results

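RNA of brain, liver/kidney and testis was measured in male mice of 2 species and set against a pool of the same tissue from C57BL6, a laboratory strain. Liver and kidney are named together in the labels, which do not say how the organs were combined. In each tissue there were 6 arrays of dom, 6 of mus, 6 of ssp, 3 of cas and 3 of spretus, 72 in all. The comparisons ask how far expression has diverged between sub-species of the house mouse, an early stage of separation, and between the house mouse and another species, a later one. Between 42825 and 44832 spots per array carried a value, and 20621 probes were tested in brain, 20652 in liver/kidney and 20754 in testis. For mus minus dom the median standard error of a probe's difference was 0.10 on the log2 scale in brain, 0.09 in liver/kidney and 0.09 in testis. Changes are log2 differences ± SE from limma, positive where the first-named group is likely higher. That direction assumes the deposited ratio to be sample over pool, as channel 2 holds the sample; it is not stated, and all signs would turn if it were inverted. Log2 as the scale is also an assumption.

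**Figure D1:**
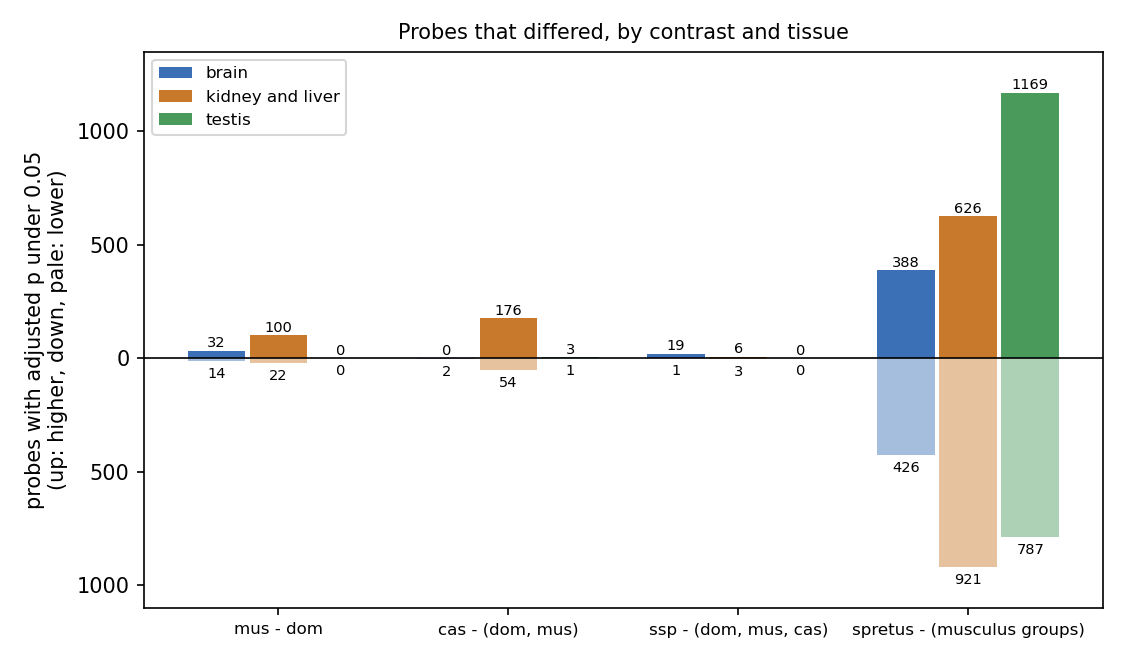
Number of probes with an adjusted p under 0.05 (vertical axis) for each contrast (horizontal axis) and tissue, higher ones drawn upward and lower ones downward in a pale shade; kidney and liver is the liver/kidney sample. The spretus contrast holds 814, 1547 and 1956 probes in brain, liver/kidney and testis, more than any contrast among the 4 musculus groups.

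In brain, 46 probes differed between mus and dom, 32 higher and 14 lower in mus. Highest above dom were Nsmce1, a subunit of a DNA repair complex (0.69 ± 0.13, adjusted p = 0.0264), Psmg4, a chaperone of proteasome assembly (0.65 ± 0.10, adjusted p = 0.00742), Ccdc82 (0.65 ± 0.12) and the transporter Slc22a15 (0.54 ± 0.12). Furthest below dom were the neuronal adhesion molecule Dscaml1 (-1.25 ± 0.23, adjusted p = 0.0264), the chromatin protein Hmga2 (-0.78 ± 0.17), Hspa5, the main chaperone of the endoplasmic reticulum (-0.72 ± 0.11, adjusted p = 0.00742), and Pigc, which acts in the synthesis of membrane anchors (-0.63 ± 0.13). Among list members, Cox4i1 of cytochrome c oxidase was lower (-0.37 ± 0.08) and Psmd6 of the proteasome higher (0.38 ± 0.08). A second probe for Hspa5 gave 0.13. All 6 mus arrays lay on the stated side of the dom mean for each of these 10 genes. Here and below, such counts use the same arrays that selected the genes, so they are no second test. Dscaml1 varied widely in dom (mean 1.25, SD 0.84 over 6 arrays), and its dom and mus arrays overlapped. Within print batch 1 (4 mus, 6 dom) limma called 0 probes, with 2885 at an unadjusted p under 0.05; the 10 named genes had adjusted p from 0.0566 to 0.182 there. The count was 3 without dom 10, dom 13 or mus 07, 5 without mus 04, 16 without dom 05 or mus 08 (the array with conflicting labels), 73 without dom 06 and 112 without mus 05. It was 324 with quantile normalisation (199 higher), 383 with array weights and 95 with print batch as a term. Slc22a15, Hmga2, Pigc, Cox4i1 and Psmd6 lost their call in 7 to 9 of 12 runs that left out 1 array.

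In liver/kidney, 122 probes differed between mus and dom, 100 higher and 22 lower in mus, and 79 by at least 1.5-fold. The highest was the cell surface proteoglycan Gpc6 (3.08 ± 0.38, adjusted p = 7.38e-05), then Lrrc8d, a subunit of volume-regulated anion channels (1.55 ± 0.25, adjusted p = 0.00188), the glutamate receptor subunit Gria3 (1.503 ± 0.21, adjusted p = 0.000488) and Tulp4 (1.26 ± 0.25). Lowest were Mtus2, a microtubule-associated protein (-1.13 ± 0.24), Hhatl (-1.06 ± 0.21), the prolactin family member Prl7a1 (-0.97 ± 0.14, adjusted p = 0.00101) and Rgs16, a regulator of G-protein signalling (-0.95 ± 0.16, adjusted p = 0.0031). Every one of the 6 mus arrays lay on the stated side for the 8 genes. Other probes for Gpc6, Lrrc8d, Gria3 and Tulp4 gave 0.09, -0.01, 0.01 and 0.05, so the change belongs to single probes. All dom and mus arrays of this tissue are in print batch 1, so the differences are within that batch; with the spread of these 12 arrays alone 244 probes were called, 185 higher and 59 lower. The count was 66 without mus 04, 72 without mus 05, 204 with quantile normalisation and 319 with array weights, and Mtus2 lost its call in 7 of 12 runs that left out 1 array.

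In testis, limma called 0 of 20754 probes between mus and dom, and 1367 had an unadjusted p under 0.05. Within print batch 1 (4 mus, 5 dom) 4 probes were called, all higher in mus, while over all batches 6 were called without dom 13 and 8 with quantile normalisation, all lower in mus. Among the testis lists, genes of sperm-egg interaction had a median of 0.08 over 11 members (camera adjusted p = 0.0896), and germline genes of the X and Y chromosomes a median of -0.08 over 9 members (adjusted p = 0.0925). Neither list passed. Adjusted over the list alone, the Y-linked transcription factor Zfy1 and the X-linked ubiquitin protease Usp26 were lower in mus, and 0 members passed over all genes.

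In brain, 2 probes were lower in cas than in the mean of dom and mus: S100pbp (-0.76 ± 0.13, adjusted p = 0.0379), lower in 3 of 3 cas arrays, and an unnamed probe. In liver/kidney the same contrast held 230 probes, 176 higher and 54 lower in cas. Mrgprx1, a receptor of the Mas-related family, was the highest named by the rule (1.33 ± 0.17, adjusted p = 0.00109), and the alpha-1-antitrypsin gene Serpina1b the next (1.32 ± 0.33, adjusted p = 0.0482). Its relative Serpina1a (0.74 ± 0.18, adjusted p = 0.0478), haemoglobin Hba-a1 (1.01 ± 0.19), the Y-linked protease Usp9y (0.65 ± 0.13), the kidney glycoprotein Umod (0.56 ± 0.13), Cox6b1 of cytochrome c oxidase (0.42 ± 0.10) and the fatty acid hydroxylase Cyp4a14 (0.38 ± 0.08) were also higher. The mitochondrial channel Vdac1 (-1.88 ± 0.39, adjusted p = 0.0196) and the immunoglobulin chain Igkc (-1.14 ± 0.27, adjusted p = 0.0411) were lower, though a second Igkc probe gave 0.13. The 3 cas arrays lay on the stated side for each of these 10 genes. Here cas shares no print batch with dom or mus; with the batch as a random block limma called 0, and the count was 108 without cas 03, 146 without dom 13 and 441 without cas 01. Without cas 03 Cox6b1 was 0.24 (adjusted p = 0.292), Serpina1a 0.50 (adjusted p = 0.327) and Serpina1b 0.97 (adjusted p = 0.292). Of 15 runs that left out 1 array, Serpina1b lost its call in 13, Serpina1a in 12 and Igkc in 9, as did S100pbp of brain in 12. The brain count was 0 without any 1 of 11 dom or mus arrays, 14 without cas 03, 320 without cas 01 and 946 without cas 02. In brain mus minus cas within print batch 2 (2 arrays each) called 0 probes by limma, with 537 at an unadjusted p under 0.05.

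In testis, 4 probes separated cas from dom and mus. Meig1, which spermatids need to form sperm, was higher (1.14 ± 0.15, adjusted p = 0.00218), as were the splicing factor Prpf40b (0.68 ± 0.11, adjusted p = 0.00905) and an unnamed probe. Gnpnat1, an enzyme of amino sugar synthesis, was lower (-0.50 ± 0.07, adjusted p = 0.00278). All 3 cas arrays lay beyond the dom and mus mean for these 3 genes. Ribosomal protein genes stood higher as a list (camera adjusted p = 0.00487, lost with an estimated correlation at 0.283; 63 members, median 0.02, mean 0.11), with 0 members past the threshold over all genes and 4 adjusted over the list alone (Rpl38, Rps12, Rps25 and Rps7). With print batch as a term the list had an adjusted p of 0.0109. The count of probes was 14 without cas 03, 11 without dom 01, 15 with quantile normalisation and 100 with array weights. For mus minus cas within print batch 2 (2 and 3 arrays) limma called 0 probes, with 1430 at an unadjusted p under 0.05.

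The ssp group differed from dom, mus and cas by 20 probes in brain, 19 of them higher. The folate receptor Folr2 (0.60 ± 0.10, adjusted p = 0.0131), the haemoglobin chains Hbb-b2 (0.60 ± 0.10, adjusted p = 0.0131) and Hba-a1 (0.41 ± 0.08, adjusted p = 0.0407), and Ndufa4 of the respiratory chain (0.46 ± 0.08, adjusted p = 0.0284) were higher in 6 of 6 ssp arrays. The teneurin Tenm1 was lower in all 6 (-0.33 ± 0.06, adjusted p = 0.0236). Ribosomal protein genes stood higher as a list (camera adjusted p = 0.000347; 64 members, median 0.10, mean 0.11), a call lost with an estimated correlation (adjusted p = 0.981); 67.2% of members lay above 0. Over all genes 0 members passed, and adjusted over the list alone 7 did (Rpl7, Rps7, Rpl39, Rps16, Rps6, Rps21 and Rps29). With print batch as a term the adjusted p was 3.93e-05, and 3 ssp arrays lie in each of batches 1 and 2. The count of probes was 297 without cas 02, the highest of the 21 runs that left out 1 array, and 10 without mus 07, the lowest; quantile normalisation gave 2 and array weights 4, and Hba-a1 lost its call in 12 of the 21 runs. Within print batch 1, ssp minus dom and ssp minus mus called 0 probes each by limma (2258 and 2173 at an unadjusted p under 0.05), and within batch 2 ssp minus mus and ssp minus cas also 0 (635 and 594).

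In liver/kidney, 9 probes separated ssp from dom, mus and cas, among them the olfactory receptor Olfr934 (0.64 ± 0.12, adjusted p = 0.0385), the membrane channel Panx1 (0.62 ± 0.12, adjusted p = 0.0472), the pseudogene Rpl29-ps1 (-0.70 ± 0.12, adjusted p = 0.0298) and Gcsam, a signalling adaptor of germinal centre B cells (-0.61 ± 0.10, adjusted p = 0.0298), each on the stated side in 6 of 6 ssp arrays. In testis limma called 0 probes, with 1009 at an unadjusted p under 0.05, and within print batch 1 also 0 for ssp minus dom and ssp minus mus (1900 and 1590). The testis ribosomal list stood higher in ssp (camera adjusted p = 0.00487; median 0.06) with 0 members past the threshold over all genes and 0 adjusted over the list alone, and the adjusted p was 0.283 with an estimated correlation and 0.748 with print batch as a term. The liver/kidney count ran from 1 (without dom 01, among others) to 47 (without ssp 03), and it was 0 with print batch as a random block, 28 with quantile normalisation and 42 with array weights. Within print batch 1, which holds all dom, mus and ssp arrays of this tissue, 106 probes were called for ssp minus dom (76 higher) and 99 for ssp minus mus (74 higher). Olfr934 lost its call in 13 and Panx1 in 15 of 21 runs that left out 1 array.

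In brain, 814 probes (3.95%) differed between spretus and the 4 musculus groups, 388 higher and 426 lower. Highest in spretus were the anoctamin Ano10 (2.22 ± 0.17, adjusted p = 3.21e-08), Nubpl, an assembly factor of respiratory complex I (1.92 ± 0.29, adjusted p = 0.000429), the channel-associated factor Tcaf1 (1.82 ± 0.19, adjusted p = 4.51e-06) and Tomm40l, a relative of the mitochondrial import pore (1.77 ± 0.14, adjusted p = 3.21e-08). Lowest were the olfactory receptor Olfr948 (-1.89 ± 0.47, adjusted p = 0.0235), the Ras regulator Nf1 (-1.59 ± 0.32, adjusted p = 0.00617), Gpc6 (-1.57 ± 0.38, adjusted p = 0.0204) and Endod1 (-1.47 ± 0.31, adjusted p = 0.0073). Other probes gave 0.21 and 0.07 for Nf1 and 0.26 for Gpc6. All 20 named genes lay on the stated side of the musculus mean in 3 of 3 spretus arrays, and 7 of them did not overlap with any musculus array.

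By list, the brain's cell types showed few changed genes, but 3.95% of all probes changed, so lists this short would hold few by chance too. Over all genes, 0 members changed among 9 neuronal, 10 GABA interneuron, 9 myelin and 8 microglial genes, by limma, and 1 of 8 astrocyte genes (S100b) fell. Of 64 ribosomal protein genes 5 rose and 2 fell (12 and 6 adjusted over the list alone), with Rpl35 at 0.59 ± 0.12, Rps12 at 0.54 ± 0.11 and Rpl3 at -0.46 ± 0.12, and the list as a whole did not pass (adjusted p = 0.902). Of 77 genes of oxidative phosphorylation 0 rose and 3 fell (1 and 4 adjusted over the list alone), led by Cox6a2 (-0.56 ± 0.10), Cox4i2 (-0.40 ± 0.09) and Atp5c1 (-0.31 ± 0.08). Heat shock genes moved both ways, Hsph1 up (0.49 ± 0.13) and Hspa5 down (-0.51 ± 0.11; -0.13 on a second probe). The immunoglobulin chain Ighm (0.53 ± 0.11; -0.26, -0.15 and 0.10 on other probes), the clock repressor Bhlhe40 (0.46 ± 0.11) and the glutathione transferase Gstt2 (0.36 ± 0.10) were higher, and the proteasome subunit Psmd6 was lower (-0.31 ± 0.09). Within print batch 2, spretus minus mus kept the call of 6 of the 20 genes (Ano10, Olfr948, Nf1, Gpc6, Endod1 and Rpl3), and 58 probes were called in all, while for spretus minus cas 0 probes were called by limma, with 2893 at an unadjusted p under 0.05. Of these 6, Olfr948, Nf1 and Endod1 share one profile over the brain arrays (pairwise r from 0.876 to 0.951), so they are not separate observations. With spretus minus ssp (3 arrays each) 5 probes were called, and 0 of the 20 genes passed. Against mus, however, Hspa5 was only -0.03 ± 0.14 (adjusted p = 0.931) and Nubpl 1.06, and against cas Hspa5 was -0.29 and Cox6a2 -0.34. The count was 361 without spretus 01, 458 without spretus 02, 377 without spretus 03, 1397 without cas 03, 1201 with quantile normalisation and 3187 with array weights. Without spretus 02 Hsph1 was 0.20, Rps12 0.35 and Rpl35 0.40, and Psmd6 lost its call in 18 of 24 runs that left out 1 array.

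In liver/kidney, 1547 probes (7.49%) differed, 626 higher and 921 lower in spretus, and 491 by at least 1.5-fold. Highest were the actin-binding Tmsb10 (2.54 ± 0.33, adjusted p = 4.76e-05), the signal peptide peptidase H13 (2.17 ± 0.25, adjusted p = 1.43e-05), the endosomal GTPase Rab4b (2.13 ± 0.32, adjusted p = 0.000235) and Tex261 (1.80 ± 0.33, adjusted p = 0.00187). Lowest were Olfr948 (-1.99 ± 0.44), the ribosomal Rpl41 (-1.97 ± 0.44), Gpc6 (-1.78 ± 0.40) and the splicing protein Snrpc (-1.78 ± 0.48), with adjusted p from 0.00725 to 0.0228. Second probes gave -0.15 for Tex261 and 0.16 for Gpc6. Of the 43 named genes 42 lay on the stated side in 3 of 3 spretus arrays, and Gsta2 in 2 of 3. Only 10 of the 43 did not overlap with any musculus array. Olfr948, Rpl41, Gpc6, Snrpc and Tex261 did overlap. Array spretus 02, alone in print batch 3 in this tissue, carried part of several values: without it Tmsb10 was 1.56 and Rab4b 1.15, and 955 probes were called, 574 higher and 381 lower. Within print batch 2 limma called 0 probes for spretus minus cas, with 1550 at an unadjusted p under 0.05; Tmsb10 was 1.32 and Rab4b 1.05 there. With the batch as a random block 113 probes were called, with quantile normalisation 901 and with array weights 719 (428 higher and 291 lower).

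Genes of hepatocytes stood lower in spretus as a list (camera adjusted p = 0.0109; 12 members, median -0.27, mean -0.31), and the call was lost with an estimated correlation (adjusted p = 0.393) and without spretus 02 (adjusted p = 0.143), where the median was still -0.22 and 10 of 12 members were lower, against 11 with all arrays. The list had a median of -0.29 for spretus minus cas within print batch 2, with 8 members lower and 4 higher, Ahsg among the latter (0.04 ± 0.20, against -0.39 pooled), Alb at -0.36 and Trf at -0.28. Over all genes 0 rose and 5 fell, and adjusted over the list alone 6 fell: the plasma proteins Trf (-0.48 ± 0.10), Fgb (-0.42 ± 0.10), Alb (-0.63 ± 0.16), Fgg, Ahsg and Hpx. The list's median per array was -0.09 in spretus 01, -0.19 in spretus 02 and 0.15 in spretus 03, against 0.08 to 0.33 in the other arrays of this tissue. As the labels do not say how the organs were combined, the share of liver in a sample cannot be told from levels within liver. Without spretus 02 Alb was -0.27 (adjusted p = 0.337). Of 11 kidney genes Umod rose (0.72 ± 0.12, adjusted p = 0.000957; 0.27 ± 0.12, adjusted p = 0.683, for spretus minus cas within batch 2, as it is also high in cas) and the glucose transporter Slc5a2 fell (-0.40 ± 0.11), and the list did not pass (adjusted p = 0.701; median -0.04, mean 0.09, of opposite sign).

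Metabolic genes of liver/kidney changed one by one. Of 24 genes of xenobiotic metabolism 4 rose and 1 fell (5 and 2 adjusted over the list alone), among them Cyp2b13, which is female-biased in mouse liver (1.06 ± 0.09, adjusted p = 1.04e-07, but 0.05 on a second probe), Gsta2 (0.73 ± 0.19) and Gstp1 (-0.47 ± 0.09). Idi1, the isomerase of the sterol pathway, rose (1.04 ± 0.13, adjusted p = 3.24e-05), 1 of 12 genes of cholesterol synthesis. Cyp27a1, which starts the acidic bile acid pathway, fell (-0.79 ± 0.17), as did the iron hormone Hamp (-0.51 ± 0.12), the fasting hormone Fgf21 (-0.45 ± 0.13), the lipogenic Thrsp (-0.34 ± 0.11) and Cux2 (-0.37 ± 0.09). Of 12 interferon-response genes the antiviral synthetase Oas1a rose (1.19 ± 0.13, adjusted p = 4.04e-06), while Rsad2 (-0.44 ± 0.10), Mx2 (-0.46 ± 0.14) and Gbp2 fell. In the clock list Bhlhe40 rose (1.00 ± 0.12, adjusted p = 1.41e-05) and Nr1d2 (-0.57 ± 0.12) and Dbp (-0.71 ± 0.15) fell. Without spretus 02 the values were -0.38 for Cyp27a1, -0.22 for Hamp, -0.17 for Rsad2, -0.17 for Cux2, -0.32 for Nr1d2 and -0.42 for Dbp. Gsta2 was 0.25 and Fgf21 -0.18 without spretus 01, and Thrsp -0.20 without spretus 03; Thrsp lost its call in 16 and Mx2 in 15 of 24 runs. For spretus minus cas within print batch 2, Rsad2 was -0.22 and Cux2 -0.21.

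Among the remaining lists of this tissue, the class II antigen presentation gene H2-Aa fell (-0.60 ± 0.12; -0.30 on a second probe), the haemoglobin Hbb-b2 rose (0.74 ± 0.22) and the red cell membrane protein Epb42 fell (-0.61 ± 0.16). The chaperone Hspa1a fell (-0.66 ± 0.15) and Hspb1 rose (0.26 ± 0.07), and the Y-linked initiation factor Eif2s3y rose (0.38 ± 0.11). Of 63 ribosomal protein genes 2 rose and 5 fell (3 and 6 adjusted over the list alone), with Rpl28 at 0.72 ± 0.13 and Rpl14 at -0.54 ± 0.13. Of 78 genes of oxidative phosphorylation 2 rose and 3 fell, including Cox8a (-0.53 ± 0.13); by probe, the assembly factor Ndufaf8 was lower (-0.33) and the pseudogene Atp5k-ps1 higher (0.26). Of 38 proteasome genes 2 rose and 2 fell (2 and 4 adjusted over the list alone), with Psmb5 at 0.95 ± 0.24, Psma2 at 0.45 ± 0.12 and Psmd8 at -0.64 ± 0.16. Of 18 glutathione transferases 3 rose and 1 fell (4 and 2 adjusted over the list alone), with Gstt2 at 0.43 ± 0.07. Without spretus 02 the values were 0.24 for Hbb-b2, -0.35 for H2-Aa, -0.37 for Epb42, -0.35 for Hspa1a and 0.21 for Psmb5, and without spretus 01 they were 0.15 for Psma2 and 0.19 for Eif2s3y. The values of spretus minus cas within print batch 2 were 0.29 for Psmb5, -0.28 for Hspa1a, 0.37 for Rpl28 and 0.43 for Hbb-b2.

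In testis, 1956 probes (9.42%) differed between spretus and the 4 musculus groups, 1169 higher and 787 lower. Quantile normalisation gave 489, fewer than the 1201 of brain and 901 of liver/kidney, and no centring gave 1961, 980 higher and 981 lower. Highest were the transcriptional coactivator Edf1 (2.91 ± 0.16, adjusted p = 1.33e-11), the myosin light chain Myl12a (2.65 ± 0.15, adjusted p = 2.14e-11), the DNA repair factor Aplf (1.84 ± 0.11, adjusted p = 6.64e-11) and the collagen Col25a1 (1.84 ± 0.37, adjusted p = 0.00287). Lowest were Rsrp1 (-1.46 ± 0.24, adjusted p = 0.000202), Meig1 (-1.36 ± 0.14, adjusted p = 7.65e-07), Gpc6 (-1.16 ± 0.25, adjusted p = 0.0042) and Ldhc, the lactate dehydrogenase of spermatocytes and sperm (-1.03 ± 0.18, adjusted p = 0.00038). Col25a1 rests on 2 spretus arrays far apart (mean 1.73, SD 2.09); within print batch 2 it was 1.72 ± 0.94 for spretus minus cas (adjusted p = 0.535). Other probes gave -0.07 for Gpc6. Each measured spretus array lay on the stated side for all 27 named genes, and 17 genes did not overlap with any musculus array. Within print batch 2, spretus minus cas called 128 probes and 9 of the 27 genes, by a fit that shares its spretus and cas arrays with the pooled one. These were Edf1 (2.90 ± 0.35), Myl12a (2.70 ± 0.14), Aplf (1.89), Rsrp1 (-1.69), Meig1 (-2.08 ± 0.12), Gpc6 (-1.25), Hspb1 (1.34 ± 0.10), Rps21 (0.71) and Psma7 (1.21). Also within it, spretus minus mus called 89 probes and 6 of the 27 genes (Myl12a, Aplf, Rsrp1, Hspb1, Rps21 and Psma7); Edf1 was 2.81 (adjusted p = 0.059), Meig1 -0.55 (adjusted p = 0.208) and Gpc6 -0.89 (adjusted p = 0.0709). The count was 785 with print batch as a term and 1042 without spretus 02.

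Germ cell genes of the testis lists changed singly. Of 13 spermatid genes 0 rose and 2 fell (1 and 2 adjusted over the list alone), Odf1 of the sperm tail (-0.35 ± 0.10) and the protamine Prm1 (-0.55 ± 0.17), and the list as a whole did not pass (adjusted p = 0.823; median -0.08). Of 13 meiotic genes Ldhc fell, 0 of 8 spermatogonial genes changed, and of 11 genes of sperm-egg interaction Zan, which binds the egg coat, rose (0.88 ± 0.13, adjusted p = 4.49e-05). Sox9 of Sertoli cells rose (0.30 ± 0.07), and Clu gave 0.65 ± 0.09 on one probe and -0.63 on another. Of 7 Leydig cell genes, 9 germline genes of X and Y and 8 epididymal genes 0 passed over all genes, by limma; adjusted over the list alone 2 epididymal genes were higher (Spag11a and Defb2). Ighm rose (0.90 ± 0.09, adjusted p = 3.91e-07; 0.26, 0.12 and -0.08 on other probes), and Rhag of red cells (-0.23 ± 0.06) and the clock factor Npas2 (-0.28 ± 0.08) fell. The small heat shock protein Hspb1 rose (1.33 ± 0.07, adjusted p = 1.17e-11), as did the collagen chaperone Serpinh1 (0.37 ± 0.08), while Hspa5 fell (-0.59 ± 0.16). Second probes gave 0.02 for Serpinh1 and -0.01 for Hspa5. Odf1 was -0.23, Prm1 -0.41 and Npas2 -0.20 without spretus 02, and Prm1 lost its call in 19 of 24 runs. For spretus minus cas within print batch 2, Hspa5 was -0.23 and Rhag -0.12.

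Of 63 ribosomal protein genes in testis 6 rose and 4 fell (6 and 7 adjusted over the list alone), with Rps21 at 0.76 ± 0.08, Rps24 at -0.49 ± 0.10 and Rpl3l at -0.26 ± 0.05. Of 78 genes of oxidative phosphorylation 1 rose and 5 fell (1 and 4 adjusted over the list alone), with Uqcrc1 at 0.37 ± 0.10, Atp5j2 at -0.44 ± 0.08 and Ndufv2 at -0.30 ± 0.09, and the list did not pass (adjusted p = 0.348). The proteasome subunits Psma7 (1.17 ± 0.11, adjusted p = 6.76e-08) and Psmd4 (0.49 ± 0.14) rose, 2 of 38 proteasome genes. Uqcrc1 was 0.10 without spretus 03, and Ndufv2 -0.20 without spretus 02.

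Over all probes, on median-centred values, expression divergence from spretus differed between the 3 tissues by less than its errors, but quantile normalisation set testis lower. The mean over the 4 musculus groups was 0.0289 ± 0.00291 squared log2 units (jackknife SE) in brain, 0.0277 ± 0.00443 in liver/kidney and 0.0288 ± 0.00907 in testis; with quantile normalisation it was 0.0326, 0.0263 and 0.0167. Between mus and dom it was 0.0121 ± 0.00472 in brain, 0.00974 ± 0.00304 in liver/kidney and 0.00429 ± 0.00639 in testis, where it was smaller than its error. Over the 6 pairs of musculus groups the means were 0.00633 ± 0.00574, 0.0121 ± 0.00342 and 0.00457 ± 0.00416. In brain spretus stood further from mus (0.0395 ± 0.0032) and ssp (0.0382 ± 0.00425) than from dom (0.0228 ± 0.00249) and cas (0.0149 ± 0.0104). Arrays of print batch 1 alone gave 0.0136 ± 0.00511 for mus and dom in brain and 0.00969 ± 0.00788 in testis. Within batch 2, spretus and cas differed by 0.0237 in brain, 0.0266 in liver/kidney and 0.0237 ± 0.00773 in testis. Inside single groups, batches 1 and 2 of mus differed by 0.0209 in testis (4 and 2 arrays) and by 0.00424 in brain. Those of ssp differed by 0.00341 ± 0.0046 in brain. The testis value within mus thus lay near that between spretus and cas, so batch may add to divergence there. Leaving out the 1% of probes with the largest squared difference lowered the spretus value in liver/kidney to 0.0147 and in testis to 0.0181, and the mus and dom value to 0.00673 in brain and 0.00375 in liver/kidney.

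**Figure D2:**
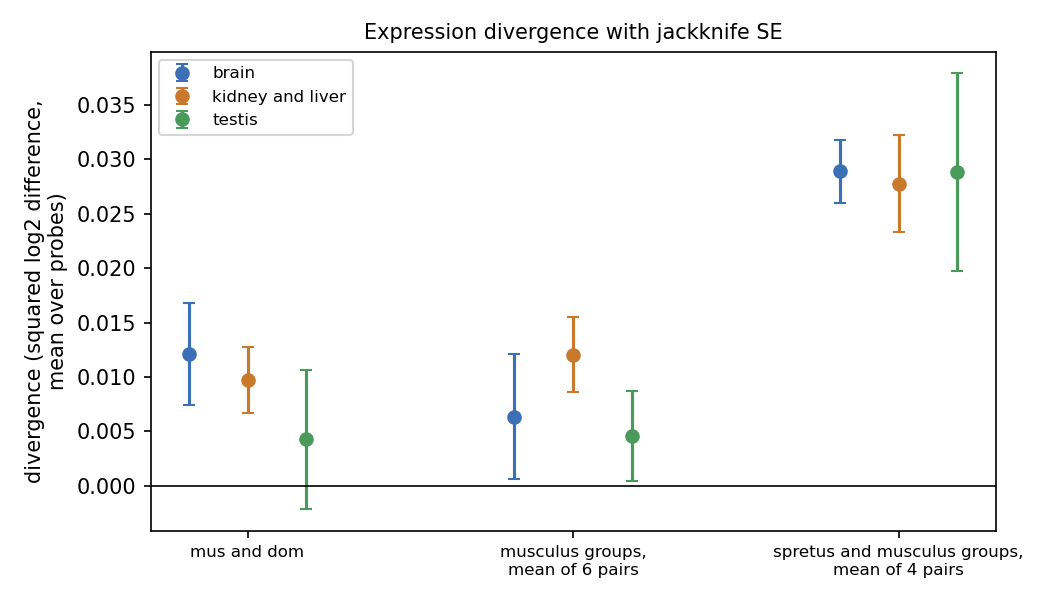
Expression divergence (vertical axis, mean squared log2 difference between group means after removal of the replicate spread) for mus and dom, for the mean of 6 pairs of musculus groups and for the mean of 4 pairs with spretus, by tissue; bars are jackknife SE. The spretus values lie between 0.0277 and 0.0289 in the 3 tissues, above the values among musculus groups. Print batches 1 and 2 within mus, not drawn, differed by 0.0209 in testis.

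Tested directly, the spretus difference was unequal between brain and liver/kidney for 380 of 18229 probes, between brain and testis for 527 and between liver/kidney and testis for 1110. Quantile normalisation gave clearly lower counts for the comparisons with testis. Tcaf1 was higher in spretus by 1.47 log2 more in brain than in liver/kidney (adjusted p = 7.66e-06) and Tomm40l by 1.34 (adjusted p = 1.29e-05). Edf1 was higher in testis by more than in brain (-2.65, adjusted p = 8.56e-18) or liver/kidney (-2.86, adjusted p = 4.11e-19). For brain against liver/kidney, Tmsb10 (-1.77, adjusted p = 0.00129) and Idi1 (-0.88, adjusted p = 0.00201) were higher in spretus by more in liver/kidney. For mus minus dom, 8 probes differed between brain and liver/kidney, with Dscaml1 at -1.24 (adjusted p = 0.0269), and 32 between liver/kidney and testis, with Gpc6 at 2.53 (adjusted p = 0.00275), Gria3 at 1.34 (adjusted p = 0.00119) and Prl7a1 at -0.91 (adjusted p = 0.00726). Between brain and testis limma called 0, with 929 at an unadjusted p under 0.05. Quantile normalisation gave higher counts for mus minus dom in each pair of tissues, so the 0 depended on the normalisation. For cas the counts were 359, 8 and 63 for brain against liver/kidney, brain against testis and liver/kidney against testis. These counts depended on the arrays: without those outside print batches 1 and 2 they were 48, 27 and 214, and quantile normalisation gave 107 for the first. Serpina1b (-1.43, adjusted p = 0.00861), Mrgprx1 (-1.04, adjusted p = 0.0182) and S100pbp (-0.94, adjusted p = 0.0313) were lower in the brain's cas difference than in that of liver/kidney. For ssp they were 2, 0 (2094 at an unadjusted p under 0.05) and 4.

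Probes changed in spretus recurred across tissues more often than independent lists would. Brain and liver/kidney shared 207 probes changed the same way, where 30.8 were to be had by chance, with 2 opposite; brain and testis shared 161 (38.0 by chance) with 6 opposite, and liver/kidney and testis 161 (70.2 by chance) with 22 opposite. In all 3 tissues 51 probes changed the same way, 35 higher and 16 lower, against 1.38 by chance, while 3338 of the 3793 probes changed anywhere did so in exactly 1 tissue. Genes of this set, chosen after their values were seen, include the homeobox gene Hoxd10 (0.93 in brain, 1.76 in liver/kidney, 0.48 in testis), the lipid kinase Pip4k2a (0.86, 1.05 and 0.62), the laminin chain Lama3 (0.67, 0.68 and 0.73), the cytoskeletal Pdlim1 (-1.30, -1.26 and -0.88) and the chromatin factor Cecr2 (-0.73, -1.11 and -0.58). Tissues of one animal share a genome and, for most spretus arrays, a print batch. For mus minus dom, 2 probes were shared between brain and liver/kidney (0.17 by chance).

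Of 470 X-linked genes tested per tissue, 2.77% changed in spretus in brain, 7.45% in liver/kidney and 8.51% in testis, against 4.49%, 8.58% and 10.2% of autosomal genes. By Fisher's exact test, two-sided, no contrast or tissue passed after adjustment (adjusted p = 1 in each).

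**Figure D3:**
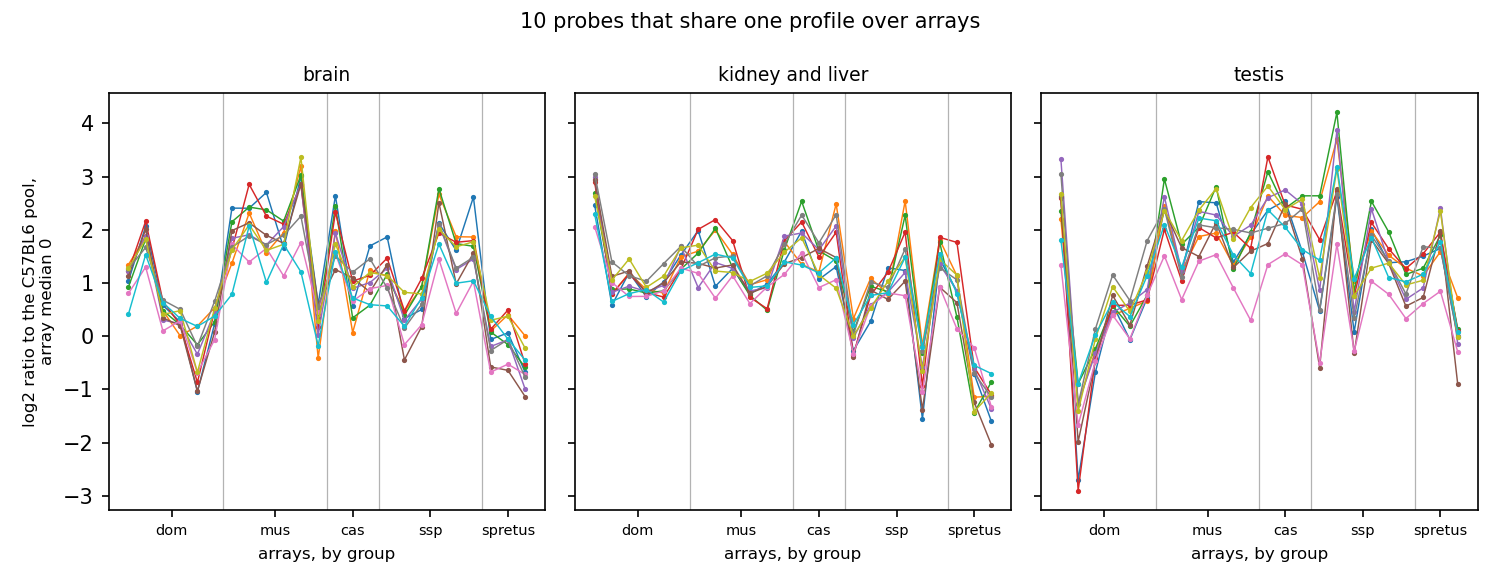
Log2 ratio to the pool (vertical axis) on each array (horizontal axis, by group) of 10 probes that follow one profile in brain, liver/kidney (kidney and liver) and testis, one colour per probe, with lines joining arrays only to guide the eye. The profile is the mean of 5 of them (Olfr948, Nf1, Endod1, Rpl41 and Snrpc), which were among the lowest in spretus; the 10 probes rise and fall together over the arrays.

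The 6 probes named as lowest in spretus in brain or liver/kidney (Olfr948, Nf1, Gpc6, Endod1, Rpl41 and Snrpc) had high pairwise correlations over the 24 arrays of a tissue, as deviations from group means. The medians were 0.848 in brain, 0.819 in liver/kidney and 0.784 in testis, against highest values of 0.394, 0.574 and 0.476 in 1000 random sets of 6 probes called lower in spretus. Gpc6 did not follow the others: its correlations with them were 0.242 to 0.458 in brain, -0.361 to -0.17 in liver/kidney and -0.515 to -0.266 in testis. The 8 probes highest in spretus gave medians of 0.0473, 0.0525 and 0.0379. Gpc6 was left out after these values were seen, and the mean of the other 5 was taken as a profile, which those 5 follow by construction. Of 20589 probes, 10 had r above 0.8 with it in all 3 tissues, the 5 themselves and 5 more. Of the 10, 4 were called for spretus in brain, 9 in liver/kidney and 0 in testis. Within print batches 1 and 2 the median correlations of the 5 probes were 0.923 and 0.783 in brain, 0.918 and 0.822 in liver/kidney and 0.817 and 0.736 in testis.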

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

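The counts of splits and the restriction of the tissue model to complete probes are tests chosen after the results were seen; the comparisons between tissues themselves were planned.

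Group differences that were unequal between tissues were tested in limma with the tissue as part of the contrast. For spretus, 380 probes were unequal between brain and liver/kidney, 527 between brain and testis and 1110 between liver/kidney and testis. In 100 splits of the same animals into groups of the same sizes, 1 split each, the real one, gave as many. This argues against chance for these counts, though no adjustment was made over the results tested by splits. The splits of this paragraph took no account of print batch, so they cannot tell group from batch. The highest other splits gave 270, 267 and 538. With quantile normalisation the last count fell below its highest other split, and no splits were run with that normalisation. For cas the counts were 359, 8 and 63, with highest other splits of 92, 48 and 15. Only the real split gave as many for the first and last (1 of 100 splits), which argues against chance for the last. Without the arrays outside print batches 1 and 2 the first fell below its highest other split, so chance is not excluded for it. Nor is it for brain against testis (9 of 100), where another split gave several times the real count. The cause of that high split was not tested. Mus minus dom had 8 probes unequal between brain and liver/kidney (2 of 100 splits, highest other 24). Chance is not excluded for them, as another split gave more, for a reason that was not tested. Between liver/kidney and testis 32 were unequal (1 of 100, highest other 24), which argues against chance but not against print batch. In liver/kidney all mus and dom arrays are in batch 1. In testis mus 07 and 08 are in batch 2 and dom 01 in batch 4. Between brain and testis limma called 0, with 929 at an unadjusted p under 0.05, so all 100 splits gave as many and the highest gave 5. For ssp, 2 probes were unequal between brain and liver/kidney (2 of 100 splits, highest other 2). Another split gave as many, so chance is not excluded for them. Between liver/kidney and testis 4 were unequal (1 of 100, highest other 2), which argues against chance, though the count is small. For brain against testis limma called 0, with 2094 at an unadjusted p under 0.05. There all 100 splits gave as many, and the highest gave 9.

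Single arrays stood far from the rest of their group for several named genes; the test was a gap to the nearest array that was large against the range of the group. Of 369 groups tested 37 met it (10.0%, where chance gives about 5%, or 1 in 20). Array dom 01 in liver/kidney held 6 of them and dom 01 in brain 4. The correlation of dom 01 with the rest of its group in brain was also the lowest (0.143, nearest 0.242).

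In brain, dom 01 was high for Hmga2 (0.88, nearest -0.28), S100pbp (0.26, nearest -0.04) and Rps12 (0.57, nearest 0.17), and dom 13 low for Tomm40l (-0.31, nearest -0.07) and Hsph1 (-0.45, nearest -0.13). Folr2 was low in dom 03 (-0.24, nearest 0.05), and Cox4i2 was high in dom 10 (0.29, nearest 0.08) and mus 05 (0.26, nearest 0.12). Ndufa4 was low in mus 05 (-0.46, nearest -0.11). Array ssp 04 was low for Ano10 (-1.08, nearest -0.12) and Nubpl (-1.66, nearest -0.18), which are high in spretus. Array mus 08, whose labels disagree, was low for Nf1 (0.54, nearest 1.67) and Ighm (-0.28, nearest -0.08).

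In liver/kidney, dom 01 stood apart for Olfr948 (2.93, nearest 1.40), Rpl41 (2.70, nearest 1.26) and Snrpc (2.96, nearest 1.49), which share one profile over arrays, and for Igkc (0.68, nearest -0.38), Panx1 (-0.73, nearest -0.37) and Nr1d2 (-0.28, nearest -0.01). Hba-a1 was high in dom 05 (1.00, nearest 0.45), Eif2s3y in dom 03 (0.25, nearest 0.07) and Thrsp in ssp 05 (0.46, nearest 0.14). Low values were Tmsb10 in dom 13 (-0.28, nearest -0.09), Mtus2 in mus 03 (-2.55, nearest -2.05), Tex261 (-0.75, nearest -0.16) and Fgb (-0.50, nearest -0.10) in ssp 06, and Rpl14 in ssp 04 (-0.0274, nearest 0.13).

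In testis, Myl12a was high in mus 07 (0.69, nearest 0.18) and Aplf in mus 04 (0.0634, nearest 0.01), and Aplf was low in ssp 05 (-0.19, nearest 0.02). Clu was high in mus 08 (0.28, nearest -0.04), Npas2 in dom 13 (0.14, nearest -0.09) and Ndufv2 in mus 07 (0.25, nearest 0.04) and ssp 04 (0.43, nearest 0.06). Rpl3l was low in dom 13 (-0.11, nearest -0.00104) and Atp5j2 in dom 01 (-0.25, nearest -0.07).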

How the results depend on the processing

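The alternatives that use print batches, and the tissue fit of all probes without a block, were chosen after seeing the data; the others were planned. A robust prior (12 results), the tissue fits with no block (12), the replicate block (15) and removal of the 1% of probes with the largest spread (6) moved no count or divergence by over 1.5 times or over its error. The same animal number in different groups was not a pairing; as a block it gave 38, 2, 16 and 773 changed probes in brain, 120, 220, 8 and 1501 in liver/kidney and 0, 4, 0 and 1936 in testis for mus minus dom, cas, ssp and spretus, and it left the number of called lists as it was. It lost the call of 3 of 131 named genes. No named gene turned its sign in the alternatives run for named genes, which are the replicate block and those of the next sentence. Calls were lost by 3 named genes with no centring, 37 with quantile normalisation, 17 of 66 with print batch as a term, 50 of 65 with it as a random block, 26 of 129 without arrays outside batches 1 and 2, and 82 of 131 when some single array was left out. Except where the cause is stated, the cause was not tested. The number of arrays limits most counts, as 9 of 12 moved with 3 animals per group, while mus minus dom, cas and ssp in testis did not (0, 4.5 and 0); signal over background is not known here, as only ratios were used.

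Counts of changed probes are given as mus minus dom, cas, ssp and spretus. With quantile normalisation brain gave 324, 0 and 2 for the first 3, liver/kidney 204 for mus minus dom, 28 for ssp and 901 for spretus, and testis 8, 15 (93.3% higher, against 75%), 2 and 489. With array weights brain gave 383, 4, 4 and 3187, liver/kidney 319 for mus minus dom, 42 for ssp and 719 for spretus, and testis 100 for cas. With the groups of the contrast alone brain gave 29, 0 and 12, liver/kidney 250, 417 and 44, and testis 12 for cas. No centring gave 0 for cas in brain and 22 for ssp in liver/kidney, and complete probes 22 for the latter. With 1 value per symbol, fewer features are tested: cas gave 1 in brain, ssp 16 in liver/kidney and spretus 1283 in testis. Without array 08 of mus in brain the first 3 counts there were 16, 0 and 12. With 3 animals per group (median of 20 draws), brain gave 0, 0, 0 and 259.5, liver/kidney 8, 3.5, 0 and 380.0, and spretus in testis 1285.5, with fewer samples as the cause.

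Print batch as a term gave 95 for mus minus dom in brain, and 18 for cas and 785 (531 higher, 254 lower) for spretus in testis. As a random block it gave 29 and 0 for mus minus dom and cas in brain, and 0, 0 and 113 for cas, ssp and spretus in liver/kidney. Without arrays outside batches 1 and 2, brain gave 174 for mus minus dom, 14 for cas and 1397 for spretus. Liver/kidney gave 404 for cas, 36 for ssp and 955 for spretus, and testis 11 for cas. This leaves out 1 array per tissue: cas 03 in brain, spretus 02 in liver/kidney and dom 01 in testis. The brain count of mus minus dom thus moved with 1 array from outside that contrast.

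Lists called fell from 1, 1 and 2 in brain, liver/kidney and testis to 0 in each with an estimated correlation. With print batch as a term 3 were called in brain, where ribosomal proteins stood lower in mus than dom (adjusted p = 0.0346), lower in cas (adjusted p = 1.34e-06) and higher in ssp (adjusted p = 3.93e-05), and 1 in testis; without arrays outside batches 1 and 2, 0 were called in liver/kidney.

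Differences between tissues (brain against liver/kidney, brain against testis, liver/kidney against testis) with quantile normalisation were 53, 14 and 89 for mus minus dom, 107 for cas in the first, 0, 1 and 7 for ssp, and 272 and 411 for spretus in the last pair. Without arrays outside batches 1 and 2 they were 48, 27 and 214 for cas, 1, 1 and 12 for ssp and 1 for mus minus dom between brain and testis; with all probes and no block cas gave 1 between brain and testis. At 1.5-fold or more, 42, 17 and 23 probes were shared between tissues for spretus, fewer being eligible. Divergence from spretus with quantile normalisation was 0.0326 in brain and 0.0167 in testis. Without the 1% of probes with the largest squared difference it was 0.0207, 0.0147 and 0.0181 in brain, liver/kidney and testis, and for mus and dom 0.00673 in brain and 0.00375 in liver/kidney, as removal of large differences must lower it.

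Arrays were left out 1 at a time, from the groups in the contrast only. Arrays of other groups also share in the spread: without cas 03 the brain count for mus minus dom lay above the range given here. Counts in brain ran from 3 to 112 for mus minus dom and 0 to 946 for cas. For ssp they ran from 10 to 297, and for spretus from 361 to 1397. For mus minus dom they were 3 without dom 10, dom 13 or mus 07, 5 without mus 04, 16 without dom 05 or mus 08, 73 without dom 06 and 112 without mus 05. For cas they were 320, 946 and 14 without cas 01, 02 and 03, and 0 without any dom array or without mus 02, 04, 05, 07 or 08. For ssp they were 297 without cas 02, 48 without ssp 01, 34 without dom 01 or ssp 02, 13 without dom 06, mus 02, mus 04 or ssp 03, 12 without mus 08 or ssp 05, 11 without dom 03, dom 05 or ssp 06 and 10 without mus 07. For spretus they were 361, 458 and 377 without spretus 01, 02 and 03 and 1397 without cas 03. In liver/kidney counts ran from 66 to 108 for mus minus dom (66 without mus 04, 72 without mus 05), 108 to 441 for cas (108 without cas 03, 146 without dom 13, 441 without cas 01), 1 to 47 for ssp and 955 to 2125 for spretus (955 without spretus 02). That ssp count was 47 without ssp 03, 20 without cas 02, 4 without dom 13, mus 05, mus 08 or ssp 01, 3 without mus 02, 2 without cas 03 and 1 without dom 01, dom 06, mus 04, ssp 04, ssp 05 or ssp 06. In testis they ran from 0 to 6 for mus minus dom (6 without dom 13), 4 to 14 for cas (14 without cas 03, 11 without dom 01), 0 to 2 for ssp (2 without ssp 05) and 1042 to 2347 for spretus (1042 without spretus 02). Divergence from spretus ran from 0.0266 to 0.0311 in brain, 0.0241 to 0.0311 in liver/kidney and 0.0238 to 0.0375 in testis, and that between mus and dom from 0.00934 to 0.0144, 0.00833 to 0.0119 and 0.000665 to 0.00899.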

Other observations

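The tests of print batch, sequence mismatch, spread, divergence and the shared profile, and the counts of splits, were chosen after the results were seen; the genes of the next 2 paragraphs were likewise chosen after their values were seen.

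Some genes set spretus apart in 1 tissue and ran the other way, or differed less, in another. The potassium channel partner Kcnip4 was higher in spretus testis by 1.13 log2 and lower in liver/kidney (-0.34), with a tissue difference of -1.47 (adjusted p = 3.44e-14). The microtubule protein Map2 was higher in testis (0.80) and lower in liver/kidney (-0.38), with a difference of -1.18 (adjusted p = 1.88e-06), and Trappc12, of a vesicle tethering complex, was higher in testis (0.49) and lower in brain (-0.43), with a difference of -0.91 (adjusted p = 1.08e-05). Eya1, a developmental transcriptional cofactor, was higher in liver/kidney (1.51) and at -0.18 in brain, with a difference of -1.69 (adjusted p = 4.86e-07). In testis the ubiquitin ligase Ubr2 (1.78), the microtubule-binding Clasp1 (1.19), the urea cycle enzyme Ass1 (1.28) and the membrane scaffold Flot2 (1.23) were higher in spretus, against 0.23, 0.07, -0.07 and 0.16 in brain, with adjusted p of the difference of 5.91e-14, 1.84e-13, 2.09e-09 and 7.87e-12.

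Meig1 in testis took opposite sides in 2 contrasts: group means were 1.08 in cas, 0.47 in ssp, -0.02 in dom, -0.11 in mus and -1.01 in spretus. For cas, the tissue difference of Meig1 was -1.15 between brain and testis (adjusted p = 4.48e-05). The acyltransferase Crat was higher in cas in liver/kidney (1.03) and at -0.01 in testis (adjusted p of the difference 0.00974), and the tight junction protein Cldn3 was higher in liver/kidney (0.84) and at -0.35 in brain (adjusted p of the difference 0.000986). The pyrimidine synthase Ctps2 (1.14 in liver/kidney, -0.03 in brain) and the cartilage collagen Col2a1 (0.91 and 0.04) differed between tissues in mus minus dom with adjusted p of 0.00723 and 0.00684. The 4 probes that set ssp apart unequally in liver/kidney and testis included the silencing factor Tnrc6a (-0.60 and 0.60), Cul2 of a ubiquitin ligase (0.43 and -0.12) and the myosin Myo9b (-0.22 and 0.78).

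More probes differed between spretus and the 4 musculus groups than among these groups, with 814, 1547 and 1956 probes. Print batch as the whole cause is argued against: each spretus array of batch 2 was held out and set against cas of that batch, over probes called from the other spretus arrays against dom, mus and ssp. The lowest slopes on the difference of those other arrays were 0.470 in brain, 0.296 in liver/kidney and 0.337 in testis, where batch alone gives 0 and the other arrays of batch 2 gave at most 0.157, 0.156 and 0.0857 in absolute value. The slopes stayed below 1, so a part of the pooled difference may come from batch or from the choice of called probes. If sequence differences only weakened binding, and only that of spretus RNA, then with 1 shift per array no probe would stand above the unweakened ones. Yet 21, 48 and 121 probes in brain, liver/kidney and testis were higher in spretus (one-sided limma test) than the level below which 95% of probes lie, with at least 10, 35 and 41 under quantile normalisation or without any 1 spretus array. This argues against weakened binding of spretus RNA alone as the whole cause. It holds if the ratio is sample over pool and the authors' scaling was 1 shift per array, which the sources used here do not state. Mismatch in general is not excluded. RNA of the 4 musculus groups may also mismatch probes, which would set spretus above their mean, and no probe sequences were used. How many of the called probes come from mismatch stays open, since centring sets the balance of higher and lower probes. A difference between the species also stays open and untested. In 100 splits of the arrays only the real one gave as many, which argues against chance. The highest other splits gave 215, 32 and 913, and the splits took no account of print batch.

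No probe was called by limma between mus and dom in testis, with 1367 at an unadjusted p under 0.05, while 46 were called in brain and 122 in liver/kidney. A larger spread between testis arrays cannot be excluded: the median standard error was 0.0875 in the fit of all 5 groups, below the 0.0989 of brain and 0.0933 of liver/kidney, but 0.0797 in a fit of dom and mus alone, above 0.0774 and 0.0767. Print batches inside mus cannot be ruled out: the 2 batches of mus differed in testis by a divergence of 0.0209, yet with the batch as a term 0 probes were called (limma). A smaller divergence in testis cannot be told from the same divergence, since brain exceeded testis by 0.985 standard errors. As the real count is 0, all 100 splits gave as many. The highest other gave 44, and what set that split apart was not tested.

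The probes of Olfr948, Nf1, Endod1, Rpl41 and Snrpc, 5 of the 6 named as lowest in spretus in brain or liver/kidney, share one profile over arrays, which the sixth (Gpc6) does not follow. Their position on the array is argued against, since the 20 neighbouring probes had a median correlation of 0.0269 with the profile. Levels of the named transcripts would be a candidate explanation, but the other probes of the same genes, 2 probes of Nf1, had a median correlation of -0.191, and too few such probes exist to decide. A sequence shared by the probes, such as one that binds a variable transcript, stays open and untested, as no probe sequences were used here.

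For the remaining counts of changed probes, 100 splits of the same arrays, the real one included, gave these results. They took no account of print batch, and no adjustment was made over the results. In brain the splits argue against chance for mus minus dom (46, highest other 1) and ssp (20, highest other 1), with 1 split as large. For cas (2, highest other 66) chance is not excluded, as 16 splits gave as many. What set the highest split apart was not tested. In liver/kidney they argue against it for mus minus dom (122, highest other 3), cas (230, highest other 7) and ssp (9, highest other 1). They cannot tell group from print batch for cas, which shares no batch with dom, mus or ssp there. With the batch as a random block cas and ssp gave 0 in this tissue. In testis chance is not excluded for cas (4), as another split gave more (2 of 100, the real one included, highest other 18). For ssp the real count was 0 in limma, with 1009 at an unadjusted p under 0.05, and 100 splits gave as many, the highest 8. For gene lists chance cannot be excluded. In brain 41 splits gave at least the 1 list called (highest other 3). In liver/kidney 32 gave at least 1 list (highest other 3), and in testis 12 gave at least the 2 lists (highest other 4).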
